A study of Rattus norvegicus with 12 samples.

How the data were processed

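Per the labels, brain RNA of rats of postnatal day 60 was extracted with Trizol, and libraries were made with a TruSeq RNA kit from 200 ng of total RNA. Per the submitters' processing notes, reads were handled with FastQC, Trimmomatic 0.36, HISAT2 and featureCounts on the rn6 build. The settings, the annotation and the strandedness of counting are not given in the sources used here. The authors deposited raw read counts per gene symbol, not normalized, in 12 files. Of these, 11 hold 1 library each and the other holds all 12 libraries, whose columns equal the single files. The table has 17337 rows and 17335 distinct names. In it 4 rows carry a repeated name, and 26 rows are named as dates by a spreadsheet, so the genes behind them are not named here. Columns left unused numbered 0. Genes that overlap, or lie antisense to each other, cannot be told apart without strand.

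Groups came from the sample titles, with 3 libraries in each of 4 groups. The design text gives 3 rats per group, and nothing else in the labels ties a library to an animal. Before averaging, the counts of the libraries of each group were compared in pairs: chi-square per degree of freedom lay between 11.6 and 227, so no 2 libraries agreed within sampling noise. Totals were 40296297 to 51669067 counts, and tested genes held 99.994% of reads. The floor for a group at 0 was 3 counts over the group, and covers counting error only.

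From the deposited counts, R 4.3.3 with edgeR 4.0.16 computed TMM factors, kept genes with filterByExpr (12850 genes), and fitted 1 quasi-likelihood model of all 12 libraries with a mean per group. SE was derived from the fold change and the quasi-likelihood F statistic. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg). CPM values were computed here from the deposited counts and TMM factors. The 33 gene lists (cell types, brain regions, pathways, and cell types that the tissue could hold besides) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01, and again with an estimated correlation. Lists with fewer than 5 tested genes were to be left out. Camera compares a list with all other genes. fry, used for the genes raised or lowered by BDL, tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

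The comparisons, tests, lists and alternatives were fixed before the data were examined. The genes to name were, per comparison, the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 1 CPM and groups that did not overlap, or the 5 with the smallest p in a direction where fewer than 5 passed. To these came the 2 members of each list with the smallest p, and Vegfc, Flt4, Prox1, Lyve1, Gfap, Aqp4, Glul, Aif1, Cldn5 and Th throughout. The text names part of the genes so chosen. Genes named only by a locus number, microRNAs and small nucleolar RNAs were counted but not named. Genes named outside that rule are said to be so.

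The alternatives fixed beforehand were DESeq2 1.42.0 size factors in the edgeR fit, DESeq2's own test, limma voom with quality weights, no filter on low counts, at least 1 CPM in 3 libraries, a fit of the compared groups alone, the replicate number as a block, a surrogate variable from sva 3.50.0, an adjusted p under 0.1, and leaving out each library in turn. Added after seeing the data were the counts without sham 2, AAV-GFP 1 and AAV-VEGFC 1, and, for AAV-GFP against BDL, libraries thinned to the lowest total and a fit without Rn18s, Rn45s and the 20 other most abundant genes.

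The tests were run first on simulated counts with known changes. With 3 libraries per group, 28.4% of genes changed by 1.5-fold, 67.2% of those changed by 2-fold and 78.8% of those changed by 4-fold were recovered for BDL against sham among 12753 genes, with 6 unchanged genes called. For AAV-GFP against BDL the shares were 44.8%, 79.1% and 92.4% among 12751 genes, for AAV-VEGFC against AAV-GFP 28.4%, 71.6% and 90.9% among 12740 genes, and for all ligated rats against sham 44.8%, 85.1% and 90.9% among 12724 genes. Each simulated gene was drawn on its own, with the same spread in every group. No simulated library therefore stood apart across many genes, as some real ones did, and these shares may overstate recovery in the real data.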

Results

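RNA sequencing was carried out on brain tissue, described in the series as middle brain, from 12 male Sprague-Dawley rats, in 4 groups of 3. Sham rats served as controls. Bile duct ligation (BDL), a surgical blockage of bile outflow that leads to cirrhosis and serves as a model of hepatic encephalopathy, had lasted 4 weeks in the other 3 groups. One ligated group received no vector, a group received an adeno-associated virus (AAV) coding for green fluorescent protein (AAV-GFP), and the last received an AAV coding for vascular endothelial growth factor C (AAV-VEGFC), a growth factor of lymphatic vessels. The vectors were injected into the cisterna magna, a fluid space behind the cerebellum, at 1.5e+11 genome copies per rat in 20 µl, a dose read from a label whose exponent appears to have lost its superscript. The deposited files held whole-number read counts per gene, with totals from 40296297 to 51669067 per library, and 12850 genes were tested. Values below are counts scaled to library size (CPM) as mean ± SD over 3 libraries, and log2 fold changes ± SE, with adjusted p from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

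The libraries carried the transcripts of forebrain neurons at high levels and those of midbrain monoamine neurons at low levels. Slc17a7, the vesicular glutamate transporter of cortical neurons, lay between 1250 and 2030 CPM in every library. Th, the rate-limiting enzyme of dopamine synthesis, lay between 0.652 and 1.7 CPM. The 15 cortex and hippocampus markers found in the files, of 20 listed, had a median of 72.4 CPM over genes, and the 17 markers of midbrain monoamine neurons found, of 18 listed, one of 0.575 CPM. Some libraries stood apart within their group. Ttr, the transthyretin gene of the choroid plexus, reached 245 CPM in sham 2 against 1.31 and 1.03 CPM in the other sham libraries. AAV-GFP 1 held 47.8 CPM of Oxt, the oxytocin gene of hypothalamic neurons, and 235 CPM of Cd74, the invariant chain of MHC class II. AAV-VEGFC 1 had the largest share of reads in ribosomal protein genes (2.83%) and the lowest mean correlation with the other libraries (0.968). AAV-VEGFC 3 lay farthest out on the second principal component (41.15) and held 27.8 CPM of Gh1, the growth hormone gene of the pituitary. The fits below without the 3 libraries that stood apart left out sham 2, AAV-GFP 1 and AAV-VEGFC 1, and kept AAV-VEGFC 3.

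The comparison of BDL with sham rats addressed what ligation did to the brain transcriptome. Red-cell genes were the clearest difference. Slc4a1, the anion exchanger of the red-cell membrane, rose from 0.283 ± 0.157 to 7.89 ± 2.1 CPM (log2 fold change 4.79 ± 0.35, adjusted p = 0.000311), and Alas2, the erythroid enzyme that starts haem synthesis, rose from 1.44 ± 0.324 to 9.13 ± 3.54 CPM (2.66 ± 0.27, adjusted p = 0.00173). The globin genes Hba1 (2.24 ± 0.19, adjusted p = 0.000816), Hbb (2.24 ± 0.29, adjusted p = 0.00798) and Hbb-b1 (2.22 ± 0.24, adjusted p = 0.00228) rose as well, although their near-identical copies share reads and the split between them is uncertain. So did Alox15, a lipoxygenase of maturing red cells and some macrophages (3.22 ± 0.29, adjusted p = 0.00088), and Lrg1, a secreted glycoprotein of the acute-phase response (1.34 ± 0.20, adjusted p = 0.0324). Egr3, an activity-induced transcription factor of neurons, fell from 88.3 ± 4.46 to 51.6 ± 3.81 CPM (-0.78 ± 0.09, adjusted p = 0.00228), and Ccdc77, a coiled-coil protein gene, fell from 9.8 ± 0.216 to 2.77 ± 0.322 CPM (-1.82 ± 0.20, adjusted p = 0.00235). In each of these genes all 3 BDL libraries lay outside the range of the sham libraries. The rule for naming the largest changes asked for this, and 3212 of all 12850 tested genes parted the groups in this way. In total 14 genes changed, 12 higher and 2 lower. Named after their values were seen, Napsa and Mmp8, the neutrophil collagenase, had 0 sham reads and were at least 44-fold and at least 37-fold higher in BDL, against a floor of 3 counts over the sham group. Leaving out a library ended the calls of Hbb (without sham 1 or sham 3), of Lrg1 (sham 2, sham 3, BDL 2 or BDL 3) and of Mmp8 (any but BDL 1), and the replicate block ended those of Lrg1 and Mmp8.

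Of the 33 gene lists fixed before the data were examined, 7 passed camera with a preset correlation of 0.01, 6 higher and 1 lower. In the blood list, 5 of 8 tested genes rose (7 adjusted over the list alone), with a median log2 fold change of 2.45 (adjusted p = 1.09e-23, and adjusted p = 0.0228 with an estimated correlation). The other members counted over the list alone were S100a8 (4.76 ± 0.86, adjusted p = 0.0958) and S100a9 (4.04 ± 0.76, adjusted p = 0.118), calcium-binding proteins of neutrophils, named after their values were seen. Each passed over all genes under 3 of 10 alternatives. The immediate early genes, which neurons switch on with activity, were lower as a list (adjusted p = 1.42e-17), with 1 of 18 fallen, 9 adjusted over the list alone and a median of -0.80. That call was lost with an estimated correlation (adjusted p = 0.114). Arc, a synaptic activity gene, was 310 ± 16.2 CPM in sham and 114 ± 50.5 CPM in BDL, and its difference did not pass (-1.44 ± 0.24, adjusted p = 0.0644), though it passed under 4 of 10 alternatives. Ier5 (-0.89 ± 0.14, adjusted p = 0.0535) and Spry4, an inhibitor of growth factor signalling (-0.67 ± 0.11, adjusted p = 0.0644), did not pass either, though each passed under 2 of 10 alternatives.

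The remaining lists that passed in BDL against sham held few or no single genes past the threshold. Among 20 genes of blood vessel endothelium and barrier, 0 passed over all genes and 1 adjusted over the list alone (list adjusted p = 0.00013, and adjusted p = 0.822 with an estimated correlation). Vwf, the von Willebrand factor of endothelium, was its leading member (0.78 ± 0.19, adjusted p = 0.337). Meninges and fibroblast matrix genes (adjusted p = 0.00795), pericytes and smooth muscle (adjusted p = 0.0137), resting microglia (adjusted p = 0.00835) and activated microglia (adjusted p = 0.0235) were higher as lists, and with an estimated correlation their adjusted p was 0.822, 0.822, 0.891 and 0.822. Leading members were Fn1, a matrix protein (0.72 ± 0.18, adjusted p = 0.348), and Clec7a, a receptor of activated microglia (2.24 ± 0.57, adjusted p = 0.348). Genes that handle ammonia and glutamate did not pass as a list (adjusted p = 0.809): Glul, the glutamine synthetase of astrocytes, was 1980 ± 36 CPM in sham and 1880 ± 17.2 CPM in BDL (-0.07 ± 0.08, adjusted p = 1). Slc38a5, a glutamine transporter, did not pass (1.25 ± 0.21, adjusted p = 0.0644), though it passed under 2 of 10 alternatives. Gfap, the intermediate filament of astrocytes (-0.11 ± 0.21), and Aqp4, their water channel (-0.18 ± 0.15), did not pass. At their highest with a library left out, the endothelial list had an adjusted p of 0.0956, the pericyte list 0.484 and the meninges list 0.894 (all without BDL 2), resting microglia 0.109 (without BDL 3) and activated microglia 0.142 (without sham 1). Without the 3 libraries that stood apart activated microglia had 0.0556 and pericytes 0.0564. The gene count rose to 103 with DESeq2 (52 higher, 51 lower), 347 with limma voom and quality weights (117 and 230), 332 in a fit of these 6 libraries alone (94 and 238), and 209 without the 3 libraries that stood apart (63 and 146), an alternative chosen after seeing the data. The excess of higher genes was thus not kept in these fits. The main test takes its spread from all 12 libraries. Chi-square per degree of freedom between replicates was 11.61 to 17.38 in sham and BDL, and up to 226.5 in the AAV groups.

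**Figure D1:**
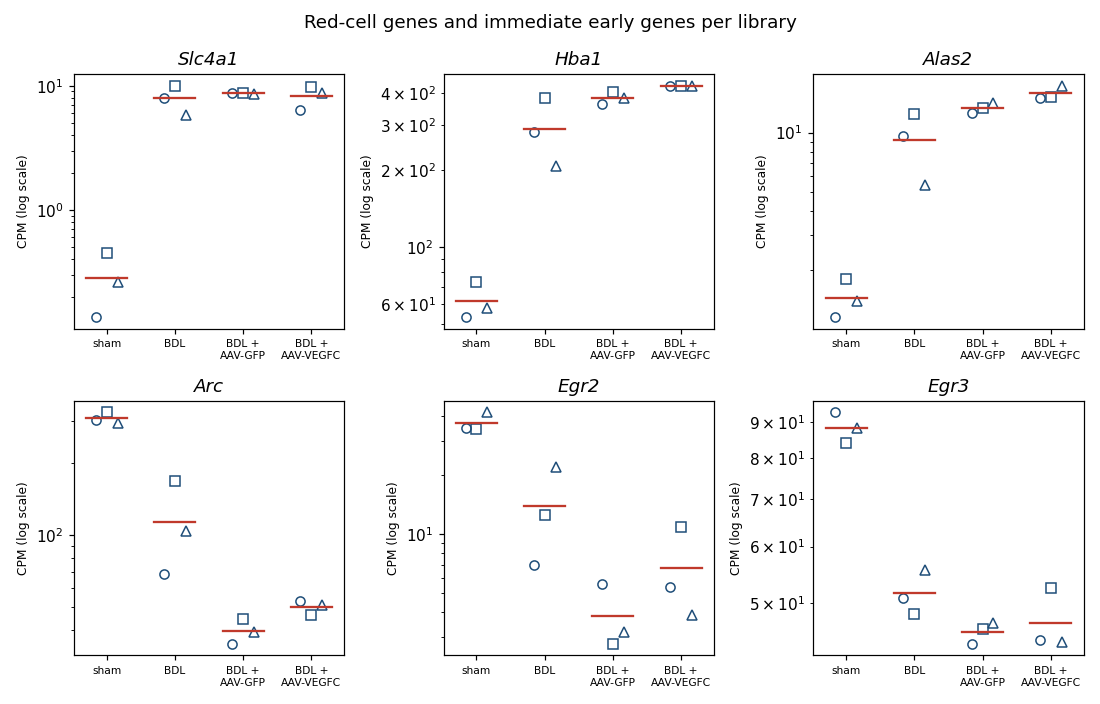
CPM on a log scale for 3 red-cell genes (Slc4a1, Hba1, Alas2) and 3 immediate early genes (Arc, Egr2, Egr3) in the 4 groups, where circles, squares and triangles are replicates 1, 2 and 3 and the red line is the group mean. All BDL libraries lie above all sham libraries for Slc4a1 (means 7.89 and 0.283 CPM) and below them for Arc (114 and 310 CPM).

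The comparison of ligated rats given AAV-GFP with ligated rats given no vector addressed the vector and its injection together. The labels give no injection for the rats without a vector, and no time of injection relative to ligation. By the edgeR fit of all libraries 795 genes changed, 127 higher and 668 lower, and the share of higher genes, 16% here, ran from 8.03% (without BDL 1) to 46.8% (limma voom) over the other fits. Snhg11, a long noncoding RNA, fell from 194 ± 23.9 to 35.4 ± 7.29 CPM (-2.45 ± 0.17, adjusted p = 3.43e-05), and Leng8, an RNA-processing factor, fell from 212 ± 20 to 48 ± 6.51 CPM (-2.15 ± 0.16, adjusted p = 4.37e-05). Lnc215, another noncoding RNA (-2.15 ± 0.11, adjusted p = 8.49e-06), Col5a1, a fibrillar collagen (-2.26 ± 0.22, adjusted p = 0.000137), Fam227a (-2.64 ± 0.23, adjusted p = 8.95e-05), Mss51 (-2.93 ± 0.47, adjusted p = 0.00355) and Rtbdn (-3.57 ± 0.60, adjusted p = 0.00494) fell too. Apold1, an early response gene of endothelium, rose from 10.2 ± 4.84 to 58.9 ± 6.28 CPM (2.53 ± 0.31, adjusted p = 0.000669). Slc39a12, a zinc transporter, rose from 1.77 ± 0.172 to 15.9 ± 0.756 CPM (3.16 ± 0.40, adjusted p = 0.000824), and Tmem252 rose by 2.30 ± 0.34 (adjusted p = 0.0021). For each of these genes the 3 AAV-GFP libraries lay outside the range of the 3 BDL libraries. The rule for naming the largest changes asked for this, and 4899 of all 12850 tested genes parted the groups in this way.

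Vascular and interferon genes were among those that rose with AAV-GFP. Of 20 genes of blood vessel endothelium and barrier 5 rose (10 rose and 1 fell adjusted over the list alone), among them Cldn5, the tight junction protein of brain endothelium, from 61.4 ± 6.92 to 116 ± 6.21 CPM (0.91 ± 0.13, adjusted p = 0.0021), and Pecam1 (0.68 ± 0.12, adjusted p = 0.00712). Of 15 pericyte and smooth muscle genes 3 rose (5 adjusted over the list alone), with Acta2, smooth muscle actin (1.42 ± 0.34, adjusted p = 0.0318), and Des, desmin (1.46 ± 0.36, adjusted p = 0.0347), as examples. Of 27 interferon response genes 3 rose (5 adjusted over the list alone), with Ifit3 (2.31 ± 0.34, adjusted p = 0.0023) and Ifit2 (0.84 ± 0.11, adjusted p = 0.00122), both antiviral effectors. Of 19 antigen presentation genes 3 rose (11 adjusted over the list alone), among them the MHC class II genes RT1-Ba (3.48 ± 0.85, adjusted p = 0.0339) and RT1-Bb (3.38 ± 0.61, adjusted p = 0.00683). RT1 genes belong to a large gene family and shared reads make their values uncertain, and AAV-GFP 1 held 235 CPM of the class II gene Cd74 against 25.7 and 22.4 CPM in the other AAV-GFP libraries. Of 15 glucocorticoid targets 2 rose (2 adjusted over the list alone), Sgk1 (1.37 ± 0.32, adjusted p = 0.0275) and Ddit4 (0.81 ± 0.15, adjusted p = 0.00707). Of 18 activated microglia genes 2 rose (2 adjusted over the list alone), the lysosomal proteases Ctsd (0.36 ± 0.07, adjusted p = 0.0104) and Ctsb (0.25 ± 0.06, adjusted p = 0.0382). The calls of Acta2, Des, RT1-Ba, Sgk1 and Ctsb ended under 4 to 7 of 10 alternatives (highest adjusted p 0.115, 0.138, 0.132, 0.117 and 0.171), and that of Ctsd without BDL 1 (0.0639).

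In all 12 lists passed camera in this comparison, all higher, from blood vessel endothelium (adjusted p = 3.41e-07) and antigen presentation (2.55e-05) through oxidative phosphorylation (0.000154), reactive astrocytes, interferon response and ribosomal proteins (0.00099 each), both microglia lists (0.00172 each), pericytes (0.00953), blood and glucocorticoid targets (0.0124 each) to Nrf2 targets (0.0381). All 12 calls were lost with an estimated correlation (smallest adjusted p = 0.628). Genes that fell included the immediate early genes Arc, from 114 ± 50.5 to 39.5 ± 4.7 CPM (-1.53 ± 0.25, adjusted p = 0.00359), and Egr2 (-1.85 ± 0.46, adjusted p = 0.036), the clock gene Per3 (-0.70 ± 0.12, adjusted p = 0.0062), and Vegfa, the main vascular growth factor (-0.55 ± 0.13, adjusted p = 0.0287). Of 18 immediate early genes 2 fell (4 fell and 1 rose adjusted over the list alone), and by camera that list did not pass (adjusted p = 0.148). The calls of Egr2 and Vegfa ended under 5 and 6 of 10 alternatives (highest adjusted p 0.142 and 0.1). Vegfc was 1.97 ± 0.469 CPM in BDL and 3.33 ± 0.44 CPM with AAV-GFP (0.76 ± 0.22, adjusted p = 0.0647), and it passed under 1 of 10 alternatives. Glul was 1880 ± 17.2 and 2330 ± 96.4 CPM (0.30 ± 0.08, adjusted p = 0.0523), and it passed under 3 of 10 alternatives (DESeq2, its size factors in edgeR, and these 6 libraries alone). Flt4, Prox1, Lyve1, Gfap, Aqp4, Th and Aif1, a marker of microglia, did not pass (smallest adjusted p = 0.367, for Gfap). RNA composition moved with the vector groups. Rn18s, an 18S ribosomal RNA, rose from 2200 ± 687 to 8780 ± 3960 CPM (adjusted p = 0.00535), and 27 of 29 tested microRNA gene rows were lower with AAV-GFP, 9 of them past the threshold, with a median log2 fold change of -0.95. Rn18s took 0.137% to 0.306% of reads in the sham and BDL libraries and 0.43% to 1.16% in the AAV libraries, and the first principal component (28.2% of the variance) parted the same 6 libraries from the other 6. No label names a batch, and vector, injection and any batch of these libraries cannot be told apart here. The count was 386 to 459 without any 1 BDL library and 413 to 415 without AAV-GFP 2 or AAV-GFP 3, and it rose to 1435 with DESeq2 (417 higher, 1018 lower), 2023 in a fit of these 6 libraries (800 and 1223), 4687 with limma voom (2195 and 2492) and 3646 without the 3 libraries that stood apart (1637 and 2009). Without AAV-GFP 1 the resting microglia list had an adjusted p of 0.23 and the interferon list 0.14, without BDL 1 the pericyte and glucocorticoid lists had 0.144 each, and without BDL 3 the blood and Nrf2 lists had 0.0617 each (Nrf2 0.0889 without AAV-GFP 1). Without the 3 libraries that stood apart 7 of the 12 lists did not pass (adjusted p from 0.0522 to 0.336).

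The comparison of AAV-VEGFC with AAV-GFP in ligated rats addressed the effect of VEGFC over that of the vector. Of 12850 genes 1 changed by the edgeR test, and 561 had an unadjusted p under 0.05. That share is below the 0.05 that would fall there on average if no gene changed. Slc39a12 fell from 15.9 ± 0.756 to 1.42 ± 1.08 CPM (-3.49 ± 0.41, adjusted p = 0.0385), a level near that of the sham and BDL rats (1.59 ± 0.262 and 1.77 ± 0.172 CPM). Its call ended under 5 of 10 alternatives, among them the replicate block and the compared groups alone (highest adjusted p 0.748). The log2 fold change stayed between -4.286 and -3.133. Rat Vegfc was 3.33 ± 0.44 CPM with AAV-GFP and 3.26 ± 0.599 CPM with AAV-VEGFC (-0.03 ± 0.21, adjusted p = 0.992). The species and sequence of the transgene are not given in the sources used here, so these counts may leave it unseen. The lymphatic genes Flt4, the receptor of VEGFC (0.43 ± 0.30), Prox1 (-0.43 ± 0.38) and Lyve1 (-0.05 ± 0.23) did not pass, and the list of lymphatic endothelium and the VEGF-C axis did not pass either (0 of 17 genes, 0 adjusted over the list alone, adjusted p = 0.7). The genes of that list had a median of only 3.74 CPM. These libraries are of bulk brain tissue, and a response of lymphatic vessels outside the tissue taken would not be seen in them. Other genes with a small p did not pass: Sik1, a salt-inducible kinase, was 7.76 ± 0.416 and 15 ± 0.914 CPM (0.95 ± 0.18, adjusted p = 0.857), Sertad1 was 8.21 ± 0.564 and 12.8 ± 1.81 CPM (0.64 ± 0.13, adjusted p = 0.857), Srsf5, a splicing factor, was 204 ± 8.98 and 251 ± 10.8 CPM, RT1-Bb was 5.64 ± 2.07 and 0.626 ± 0.533 CPM, and RT1-CE14 was 2.43 ± 0.389 and 1.13 ± 0.18 CPM. Glul was 2330 ± 96.4 and 2330 ± 299 CPM, Gfap 822 ± 138 and 629 ± 233 CPM, and Cldn5 116 ± 6.21 and 127 ± 26.8 CPM, none of them past the threshold.

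By camera 13 lists passed in AAV-VEGFC against AAV-GFP, 6 higher and 7 lower, and all 13 calls were lost with an estimated correlation (adjusted p = 0.761 for each). The immediate early genes were higher as a list (median 0.56, adjusted p = 1.51e-06), with 0 of 18 past the threshold and 5 adjusted over the list alone. Btg2, a growth-arrest gene of that list, was 27.2 ± 4.76 and 49.7 ± 13.4 CPM, and Cyr61, a matrix signalling gene, 2.98 ± 1.13 and 23.6 ± 23.3 CPM. Antigen presentation genes were lower as a list (adjusted p = 2.01e-05), with 0 of 19 past the threshold and 7 adjusted over the list alone, and without AAV-GFP 1 the adjusted p was 0.257. Immediate early genes were the only list of the 13 that passed in the same direction whichever library was left out (adjusted p at most 0.0304, without AAV-GFP 1), and without the 3 libraries that stood apart it did not pass (adjusted p = 0.0574), nor did 10 of the other 12. Ribosomal protein (3.67e-05), oxidative phosphorylation (8.32e-05), circadian clock (0.00756), striatum (0.0141) and oligodendrocyte genes (0.0375) were higher as lists. Meninges (0.0108), T, B and NK cells (0.0274), activated microglia (0.0371), interferon response, reactive astrocytes and glutamate synapse genes (0.0375 each) were lower. These values are adjusted p. Of these lists 0 had a gene past the threshold, and the AAV-GFP libraries also enter the comparison with BDL, so a list higher there and lower here rests on shared libraries. Without AAV-VEGFC 1 the cytosolic ribosomal proteins passed in the opposite direction, lower with AAV-VEGFC (adjusted p = 7.92e-05), and oxidative phosphorylation and glutamate synapse genes turned direction without passing (0.415 and 0.887). The interferon list turned without AAV-GFP 1 (0.749) and the striatum list without AAV-GFP 2 (0.854). The gene count was 0 without AAV-GFP 2, without AAV-GFP 3, without AAV-VEGFC 2 and in a fit of these 6 libraries alone, 22 without AAV-GFP 1, 9 without AAV-VEGFC 1, 10 with DESeq2, 1 with limma voom, and 1193 without the 3 libraries that stood apart. That last fit was chosen after seeing the data, by no rule fixed beforehand. Of these groups it keeps only AAV-GFP 2, AAV-GFP 3, AAV-VEGFC 2 and AAV-VEGFC 3. AAV-VEGFC 3 lay farthest out on the second principal component (41.15), so the 1193 genes may partly reflect that library.

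**Figure D2:**
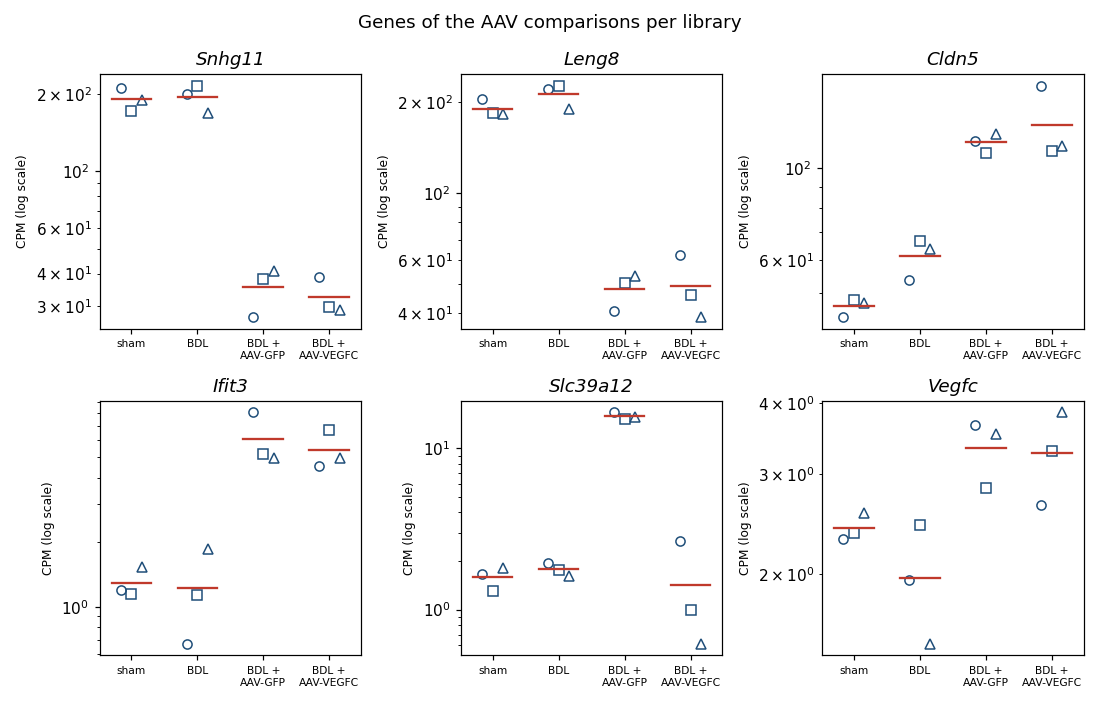
CPM on a log scale for Snhg11, Leng8, Cldn5, Ifit3, Slc39a12 and Vegfc in the 4 groups, where circles, squares and triangles are replicates 1, 2 and 3 and the red line is the group mean. Slc39a12 is high in the 3 AAV-GFP libraries (mean 15.9 CPM), and Snhg11 is lower in both AAV groups (means 35.4 and 32.3 CPM) than in sham and BDL (190 and 194 CPM).

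Whether AAV-VEGFC opposed the effect of ligation was asked with comparisons that share no library. Across 12850 genes the mean log2 difference of AAV-VEGFC from AAV-GFP had a Pearson correlation of -0.107 with that of BDL from sham (exact two-sided permutation p = 0.21 over 400 relabellings, smallest possible p = 0.01), and Spearman's rho was -0.024 (p = 0.85 by the same exact permutation). Genes are not independent replicates, and relabelled libraries gave correlations from -0.249 to 0.249. The 100 genes with the smallest p among those higher in BDL had a median log2 fold change of -0.01 under AAV-VEGFC, with 48 of 100 higher. The 100 such genes among those lower in BDL had a median of 0.05, with 59 of 100 higher. By fry neither list moved in a direction at the 0.05 level. Of the lists called by camera in BDL against sham, immediate early genes were lower there (adjusted p = 1.42e-17) and higher with AAV-VEGFC (1.51e-06). Activated microglia and meninges genes were higher there and lower with AAV-VEGFC (0.0371 and 0.0108). The other lists called there did not pass with AAV-VEGFC. With an estimated correlation none of these opposed calls held (adjusted p from 0.114 to 0.822). Of the named genes, Slc4a1 was 8.73 ± 0.0943 CPM with AAV-GFP and 8.26 ± 1.73 CPM with AAV-VEGFC, and Arc was 39.5 ± 4.7 and 49.9 ± 3.47 CPM. Without AAV-VEGFC 1 the correlation of the AAV-VEGFC effect with the BDL effect was -0.214 (exact permutation p = 0.01, the smallest it could give). The raised genes then had a median of -0.07 and the lowered genes one of 0.20, and by fry both lists passed the 0.05 level. Without AAV-VEGFC 2 (medians 0.05 and 0.01) and without AAV-VEGFC 3 (-0.01 and 0.00) the direction by fry turned in both lists, with none at the 0.05 level.

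The mean of the 3 ligated groups was compared with sham to use all 9 ligated libraries. It pools groups with and without a vector, and genes that differ between those groups enter it. Of 1287 changed genes, 388 were higher and 899 lower in ligated rats. All 14 genes called in BDL against sham were among them, 1109 of the 1287 had the same sign in BDL against sham, and 542 were also called in AAV-GFP against BDL. Both of these comparisons share libraries with this one. Of the 899 lower genes, 483 were called lower in AAV-GFP against BDL. Red-cell genes led again, with 7 of 8 blood genes raised (7 adjusted over the list alone, adjusted p = 1.21e-12, and adjusted p = 0.15 with an estimated correlation). Slc4a1 rose by 4.86 ± 0.33 (adjusted p = 2.98e-05), Alas2 by 3.11 ± 0.25 (adjusted p = 4.6e-05), S100a8 by 5.07 ± 0.81 (adjusted p = 0.00324) and S100a9 by 4.18 ± 0.72 (adjusted p = 0.0047), each higher in 9 of 9 ligated libraries than in every sham library. Immediate early genes fell, 9 of 18 (11 adjusted over the list alone, adjusted p = 4.55e-07, and adjusted p = 0.332 with an estimated correlation). Arc fell by 2.35 ± 0.18 on the log2 scale (adjusted p = 3.58e-05), Egr2 by 2.38 ± 0.32 (adjusted p = 0.00126), Egr1 by 1.32 ± 0.20 (adjusted p = 0.00259) and Nr4a1 by 1.14 ± 0.19 (adjusted p = 0.00453), each lower in 9 of 9 ligated libraries than in every sham library. Of all 12850 tested genes 1243 parted ligated from sham libraries in this way, higher or lower, and the naming rule asked for it in the largest changes.

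Vascular genes were higher in the mean of the ligated groups. Of 20 endothelial and barrier genes 12 rose (17 rose and 1 fell adjusted over the list alone, adjusted p = 2.94e-10, and adjusted p = 0.332 with an estimated correlation). Cldn5 (1.06 ± 0.12, adjusted p = 0.000338) was 46.4 ± 2.35 CPM in sham, 61.4 ± 6.92 in BDL, 116 ± 6.21 with AAV-GFP and 127 ± 26.8 with AAV-VEGFC. Emcn, an endothelial sialomucin (0.85 ± 0.13, adjusted p = 0.00255), was 6.41 ± 0.638, 8.38 ± 0.857, 13.2 ± 1.79 and 14 ± 2.39 CPM in the same order. In BDL against sham, without a vector, 0 of the 20 genes passed. Of 18 activated microglia genes 6 rose (7 adjusted over the list alone), among them Clec7a (2.36 ± 0.51, adjusted p = 0.0146), and of 21 resting microglia genes 3 rose (3 adjusted over the list alone), among them the complement gene C1qc (0.82 ± 0.22, adjusted p = 0.0421). Of 20 reactive astrocyte genes 3 rose (6 rose and 1 fell adjusted over the list alone), with Vim, vimentin (0.79 ± 0.18, adjusted p = 0.0188), and Osmr, the oncostatin M receptor (1.10 ± 0.25, adjusted p = 0.0188). Gfap did not pass (0.00 ± 0.17, adjusted p = 0.993). The calls of Clec7a, Vim and Osmr ended without any 1 of the sham libraries (highest adjusted p 0.102, 0.129 and 0.099), and that of C1qc under 7 of 16 alternatives (0.188). With an estimated correlation the adjusted p was 0.332 for activated microglia and 0.602 for resting microglia and reactive astrocytes. The reactive astrocyte list did not pass without the 3 libraries that stood apart (adjusted p = 0.112). Of 15 glucocorticoid targets 6 rose (7 adjusted over the list alone, adjusted p = 7e-04, and adjusted p = 0.332 with an estimated correlation), with Mt1a, a metallothionein (1.25 ± 0.18, adjusted p = 0.002), as an example. In BDL against sham, without a vector, 0 genes of the microglia, reactive astrocyte and glucocorticoid lists passed. The reactive astrocyte and glucocorticoid lists did not pass there either (camera adjusted p = 0.176 and 0.07). All of these lists were higher in AAV-GFP against BDL, so their rise here may follow the vector groups. Of 21 ammonia and glutamate handling genes 2 rose and 1 fell (4 rose and 1 fell adjusted over the list alone): the amino acid transporters Slc38a5 (1.46 ± 0.18, adjusted p = 0.000748) and Slc7a5 (0.33 ± 0.07, adjusted p = 0.0127) rose and, named after its value was seen, the potassium channel Kcnj10 fell (-0.29 ± 0.06, adjusted p = 0.0157). The calls of Slc7a5 and Kcnj10 ended without sham 1 or sham 3 (highest adjusted p 0.0948 and 0.127). The ammonia list did not pass (adjusted p = 0.43), and Glul did not pass (0.13 ± 0.07, adjusted p = 0.223). Neither did Aif1 (adjusted p = 0.183), Aqp4, Th, Vegfc, Flt4 or Prox1. Col11a1, a fibrillar collagen, fell by 1.48 ± 0.11 on the log2 scale (adjusted p = 2.98e-05), with 18.6 ± 0.894 CPM in sham, 16.7 ± 1.27 in BDL and 4.19 ± 0.855 with AAV-GFP. Vegfa fell by 0.50 ± 0.10 (adjusted p = 0.0108, and 0.0643 without sham 1), and it was also called lower in AAV-GFP against BDL (-0.549, adjusted p = 0.0287). Of 17 genes of lymphatic endothelium and the VEGF-C axis 3 rose (6 rose and 1 fell adjusted over the list alone, adjusted p = 0.04, and adjusted p = 0.332 with an estimated correlation), and Lyve1 (0.54 ± 0.19, adjusted p = 0.1) did not pass. That list call ended without sham 1, AAV-GFP 1, AAV-VEGFC 1 or AAV-VEGFC 2 (adjusted p from 0.0616 to 0.0945), with the replicate block (0.0564), with at least 1 CPM in 3 libraries (0.125) and without the 3 libraries that stood apart (0.243). The lymphatic list also holds genes of endothelium in general, such as Kdr, Tie1 and Tek, and the blood vessel list rose in the same comparison. Its rise is thus not particular to lymphatic vessels. In all 13 lists passed, 12 higher and 1 lower, and 0 held with an estimated correlation. The gene count was 378, 678 and 463 without sham 1, sham 2 and sham 3, 3199 without AAV-VEGFC 1, 2127 with DESeq2 (884 higher, 1243 lower), 4506 with limma voom (2052 and 2454), and 3387 without the 3 libraries that stood apart (1481 and 1906).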

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

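Genes considered for the text were refitted with DESeq2 factors, DESeq2, the compared groups, the replicate block and each library left out, but not under the other alternatives. Called genes kept their direction in 95 of 95 cases and passed throughout in 55. Uncalled genes passed under some alternative in 24 of 71 and changed sign in 12. For BDL against sham (14 genes), adjusted p under 0.1 gave 23 genes, DESeq2 103, voom 347, the 6 libraries alone 332, and the fit without the 3 libraries that stood apart, chosen after seeing the data, 209; leaving out a library gave 12 to 17. For AAV-GFP against BDL (795), the values were 1302, 1435, 4687, 2023 and 3646, a surrogate variable gave 1344, and leaving out a library gave 386 to 859. For AAV-VEGFC against AAV-GFP (1), DESeq2 gave 10, the 6 libraries alone 0, the fit without the 3 libraries 1193, and leaving out a library 0 to 22. For all ligated rats against sham (1287), adjusted p under 0.1 gave 2157, DESeq2 2127, voom 4506, a surrogate variable 2107, the fit without the 3 libraries 3387, and leaving out a library 378 to 3199.

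Lists passing camera numbered 7, 12, 13 and 13 in the same order. An estimated correlation gave 1, 0, 0 and 0. Without the 3 libraries the numbers were 8, 5, 3 and 11. Leaving out a library gave 3 to 11, 9 to 16, 7 to 14 and 12 to 16. The correlation of the AAV-VEGFC effect with the BDL effect (-0.107) ranged from -0.214 to -0.002 when a library was left out. The medians of the BDL-raised genes (-0.007) were 0.02 with 200 genes and 0.015 with the CPM filter, and ranged from -0.074 to 0.054 without a library; those of the BDL-lowered genes (0.05) ranged from -0.002 to 0.203. Without AAV-VEGFC 1 the ribosomal protein list passed in the opposite direction. The cause was not tested.

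Replicate numbers did not pair the libraries: 18 same-numbered correlations lay between -0.128 and 0.069, and 1 library was closest to its own number everywhere. With the replicate block the counts were 12, 550, 0 and 927, the lists 7, 12, 13 and 12, the correlation of t statistics -0.029 (-0.033 without the block), and the medians -0.012 and 0.057. For the 1 gene of AAV-VEGFC against AAV-GFP the block ended the call. At these depths, counting error was small beside the differences between libraries.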

Other observations

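Some clock genes were higher and others lower in ligated rats, and the circadian list did not pass (adjusted p = 0.874). Of its 13 genes 3 rose and 2 fell. Dbp (0.76 ± 0.12, adjusted p = 0.00351), Ciart (0.80 ± 0.14, adjusted p = 0.00588) and, named after its value was seen, Tef (0.29 ± 0.06, adjusted p = 0.0163) rose, while Arntl (-0.54 ± 0.12, adjusted p = 0.0177) and Clock (-0.50 ± 0.11, adjusted p = 0.0122), which drive it, fell, all by the edgeR test of all ligated rats against sham. The calls of Arntl and Clock, also named after their values were seen, ended without sham 1 or sham 3, and that of Tef without any 1 of the sham libraries. The antiviral gene Rsad2 rose by 1.29 ± 0.17 (adjusted p = 0.001), higher in 9 of 9 ligated libraries than in every sham library, and Pdk4, a brake on glucose oxidation named after its value was seen, by 1.21 ± 0.30 (adjusted p = 0.0265), a call that ended without any 1 of the sham libraries.

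The splits of the libraries below were planned, and the other tests were chosen after the results were seen. For BDL against sham (14 genes) the highest of the other splits gave 1 gene, and for AAV-GFP against BDL (795 genes) also 1. With 10 splits of 6 libraries a share under 0.05 cannot be reached, and the real split alone (1 of 10) gave as many genes in both. For AAV-VEGFC against AAV-GFP, 4 of 10 splits gave at least the 1 gene of the real split, and the highest gave 699. For all ligated rats against sham (1287 genes), 4 of 100 splits drawn gave as many, the real one included, and the highest of the others gave 4123. The bound of 0.05 fixed beforehand was wrong here, because the libraries with and without a vector differ: the 84 trios that mixed them gave at most 9 genes. Of the 16 trios from one side, a count made after the splits were seen, 4 gave as many (25%). Among these, 10 trios held AAV libraries only, and 3 of the 10 gave as many. Such a trio is set against all sham and BDL libraries, so it carries the vector difference and is no measure of chance. The other 6 trios held sham and BDL libraries only, and of these the real one alone gave as many (16.7%). The 5 other trios of sham and BDL libraries, none of them a division of sham from ligated rats, gave 351 to 781 genes. With 6 such trios a share under 0.05 cannot be reached. A chance division of the libraries therefore stays open for this count, and part of the 1287 genes may follow the parting of vector from other libraries.

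Between AAV-GFP and BDL 668 of 795 changed genes were lower, and the share of higher genes (16%) ran from 8.03% to 46.8% over the other fits. Depth overlapped between these groups, with totals of 45241784 to 49070624 counts in BDL and 46507618 to 51669067 with AAV-GFP. With every library thinned to the lowest total 746 genes changed (633 lower), but thinning had little difference in depth to remove. Rn18s, Rn45s and the 20 other most abundant genes took 6.08% to 6.3% of the counts in BDL and 6.57% to 7.52% with AAV-GFP. Left uncorrected, this would shift all other genes by -0.015 (SE 0.005) on the log2 scale. The 668 lower genes fell by at least 0.23 (median -0.62). These falls were already scaled with TMM factors, which are meant to remove such a shift, so the comparison is no test of that explanation. It shows only that the shift from these abundant genes would be small beside the falls. A fit without Rn18s, Rn45s and the 20 others gave 793 and decides nothing, since it left the scaling nearly as it was. Separate handling of the AAV libraries may have lowered the microRNA gene rows (median log2 fold change -0.95), and it cannot be told apart from an effect of the vector or of the injection, because every AAV library could share it. A response of the brain to the vector stays open and untested.

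Red-cell genes were higher in BDL than in sham libraries. More blood of unchanged makeup in the tissue may account for it: Slc4a1 rose by 2.56 more than Hba1 on the log2 scale (SE 0.40), which leaves that open, since the level of globin made by the brain itself is unknown. That SE treats the genes as independent, although both were measured in the same libraries. Pf4, a platelet gene named after its value was seen, was 0.35 ± 0.0996 CPM in sham and 0.365 ± 0.075 CPM in BDL. The neutrophil genes S100a8 (4.755) and S100a9 (4.042) had larger log2 fold changes than Hba1 (2.237). Neither passed in this comparison by the edgeR test (adjusted p = 0.0958 and 0.118). Over 10 alternatives S100a8 ran from 4.155 to 9.371 and S100a9 from 3.51 to 5.657, so the size of their rise is uncertain. The estimates of these blood-cell genes differed, and whether the genes moved alike was not tested. A change in the red cells of ligated rats stays open and untested.

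Few genes changed between AAV-VEGFC and AAV-GFP. Exchanging the labels of AAV-GFP 1 and AAV-VEGFC 1 gave 699 changed genes against 1. Exchanged labels could give this, but so could differences in the tissue taken, since both libraries stood apart in other ways, and Slc39a12 was high in AAV-GFP 1 (16.7 CPM) and low in AAV-VEGFC 1 (2.65 CPM), as labelled. The explanations cannot be told apart, and no gene is reported from the exchanged grouping. Slc39a12 itself may be among genes switched on or off between libraries without regard to group. Of 9343 genes reaching 10 CPM, 34 had a gap of at least 2 on the log2 scale between low and high libraries, and 30 of the 34 split a group. Gng2, a G protein subunit named after its values were seen, averaged 0.79 CPM in sham 1 and sham 2 and 420 CPM in the other 10 libraries. The other 4 of the 34 split no group, among them Slc39a12 and Alox15, which parts the sham libraries from the rest, so whether Slc39a12 belongs with the 30 stays open.

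Pituitary transcripts appeared in AAV-VEGFC 3 alone at a high level, with 27.8 CPM of Gh1, growth hormone, against at most 0.539 CPM elsewhere.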
